A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

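Poly(A) RNA from 6 cultures of the budding yeast strain W303 was hybridised to 6 Affymetrix yeast arrays, 1 array per culture. Per the labels' protocols, RNA was extracted with phenol and chloroform, poly(A) RNA was purified on oligo(dT) resin, and 2 µg of it was turned into biotin-labelled cRNA. The cultures fall into 3 [gar-] and 3 [GAR+] samples by their titles, and the labels describe them as separately grown cultures. The deposited table holds 1 linear signal per probe set and array, and MAS5 and GCOS are the tools named in the submitters' processing notes. Their versions, the scaling target and any detection calls are not given in the sources used here.

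The deposited signals did not share a scale. The mean of each array after removing 2% of the values at each end was 295, 295 and 250 for [gar-] cultures 1, 2 and 3, and 500, 192 and 311 for [GAR+] cultures 1, 2 and 3, so the highest was 2.60 times the lowest. The planned design had assumed a common scale and no further normalization. Before any test was run, quantile normalization of all 9335 probe sets, listed in advance as another choice, was taken for all results, and the fit without it was kept for comparison. Values were analysed as log2(normalized signal + 16). A fold change is therefore on the log2(signal + 16) scale, which understates the change of dim genes.

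Probe sets were named through the platform's annotation of 2016. Of the 9335 probe sets, 6504 had exactly 1 gene and were tested, 328 had several genes, and 2503 were unnamed in that annotation, 60 control probe sets among them. Symbols were updated through gene identifiers against the gene table of assembly R64. All 6504 were matched and 0 symbols changed. The tested probe sets stood for 5656 genes, 315 of which had more than 1. The gene table served only for names and for the order of neighbouring genes, since the files name no genome build. The array's probe sets for other species are controls, and 16 of them were too few to set a background level, so none was called.

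Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), [GAR+] against [gar-] with no covariate, and p was adjusted by the Benjamini-Hochberg method over the tested probe sets. A probe set passed at an adjusted p under 0.05. The tests are two-sided. For HXT3 an exact two-sided permutation test of the 6 values was added, which with 3 against 3 cannot give a p under 0.1. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.18. No pair of arrays held identical values, and the correlation over tested probe sets lay between 0.972 and 0.991 for every pair.

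The following were fixed before the data were examined: the test, its threshold, the alternatives, 34 gene lists and the rule for the genes that are named. The lists cover hexose transporters, glucose sensing, the use of other carbon sources, energy metabolism, stress, ribosomes, nutrient regulons, cell types, the cell cycle, the cell surface and several gene families. All but 1 had at least 4 measured genes, with 1 probe set per gene, the one of highest mean. The list of genes of the 2-micron plasmid had 0 measured members and was left out. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 33 lists. Camera with an estimated correlation and fry were alternatives. None of the calls made with the preset correlation held with the estimated one. With the latter no list passed in any fit, blocked or not, and this includes the hexose transporters, which hold HXT3. It was not tried on simulated data, so how often it finds a true shift is not known. A miss at that setting is thus no evidence against a shift. The naming rule takes up to 15 genes per direction that passed and whose groups did not overlap. It adds HXT3, STD1, PMA1, MTH1, SNF3, RGT2 and RGT1, and up to 4 passing members of each list, or 2 where none passed. Where fewer than 10 genes met the first part, it adds those of smallest unadjusted p until 10 are named. It gave 75 genes, 1 of them by its first part.

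The groups share the culture numbers 1 to 3. The deviations of same-numbered arrays from their group means correlated at 0.322, 0.347 and 0.346 over the tested probe sets, each above the limit of 0.1 set for treating the numbers as pairs, while arrays of different numbers gave -0.311 to 0.0751. The pairing comes from these correlations only: the labels do not say what a number shares. The fit with the number as a block was run beside the one without it. Standard errors, intervals, p and the genes named by smallest p come from the fit without the block unless stated.

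On data simulated from these 6504 probe sets with 200 of the brighter ones changed, the same steps called 5 of 40 changed by 1.5-fold, 30 of 40 by 2-fold and 40 of 40 at each of 4-fold, 8-fold and 16-fold, with 11 unchanged probe sets among 166 called. With 20 changed probe sets only, 3 of 20 were called at 2-fold, beside 1 unchanged probe set, and 20 of 20 at 4-fold, beside 5 unchanged. In this simulation a change of 2-fold in few of the brighter probe sets was thus mostly missed, and one of 4-fold was found. Changes were set on the log2(signal + 16) scale, and dim probe sets were not changed. Arrays were drawn independently, without a shared culture number. An unadjusted limma p under 0.05 was found for 5.17% of the unchanged simulated probe sets, against 2.98% of those tested in the data. Recovery in the data can therefore differ.

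The other settings listed in advance were a pseudocount of 1 or 64, cyclic loess or median centring in place of quantile normalization, leaving out the dimmest probe sets so that 4336 stayed, a fit without the trend, a robust fit, array weights, the culture number as a block, all probe sets but controls, 1 probe set per gene, an adjusted p threshold of 0.01 or 0.1, and leaving out each array in turn. The fit without between-array normalization, first planned for all results, became an alternative after the scales of the arrays were seen. Scaling by the trimmed mean, leaving out both arrays numbered 2 and taking HXT3 out of every list were added after the data were seen. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.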

Results

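Transcript levels were compared between budding yeast with and without [GAR+], a prion, that is, a protein-based element passed on to daughter cells without a change in DNA. Cells that carry it can use carbon sources such as glycerol although glucosamine, a glucose mimic that triggers glucose repression, is present, and [gar-] cells lack it. The cultures were W303, a common laboratory strain, grown in synthetic medium with 2% glucose to an OD600 of about 0.8. There were 3 cultures of each kind and 1 Affymetrix array per culture. Of 9335 probe sets, 6504 were tied to a single gene and tested, covering 5656 genes. Levels are MAS5 signals after quantile normalization of the 6 arrays, because the trimmed mean of the deposited signals ranged from 192 in [GAR+] culture 2 to 500 in [GAR+] culture 1. The signed values given for genes and the medians of gene lists are log2 fold changes of [GAR+] over [gar-], on the log2(signal + 16) scale.

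The comparison asked which transcripts differ between cells with and without the prion. HXT3, which encodes a low-affinity glucose transporter of the plasma membrane, fell from a mean signal of 4103 ± 473 (SD, n = 3) in [gar-] cultures to 59.0 ± 16.3 (SD, n = 3) in [GAR+] cultures. The [gar-] arrays read 4404, 4347 and 3559, and the [GAR+] arrays 58.7, 75.4 and 42.8. The linear means differ 69.6-fold. On the log2(signal + 16) scale the change was -5.80 with a standard error of 0.19, a 55.6-fold decrease with a 95% confidence interval of 41.1 to 75.1. The adjusted p from limma was 6.86e-07, and all 3 [GAR+] values lay below all 3 [gar-] values. The exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. The [GAR+] signals of HXT3 (YDR345C) were above those of 16 control probe sets for non-yeast sequences, whose highest on the same arrays were 15.1 to 20.2. HXT3 was named beforehand because it is known from work on [GAR+] as the most changed transcript. That knowledge can rest on these same arrays, so it is not independent evidence.

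HXT3 was the only probe set of the 6504 that passed, so 0 were higher and 1 was lower in [GAR+], and the next smallest adjusted p was 1.00. At an unadjusted p under 0.05 limma found 194 probe sets, 2.98% of those tested, and 441 (6.78%) with the culture number as a block, where HXT3 was again the only call. Groups did not overlap for 576 probe sets, 8.86% of those tested (10% by chance if the 6 arrays are exchangeable, which same-numbered arrays that correlate put in doubt), 287 of them higher and 289 lower in [GAR+]. For 6248 probe sets, 96.1%, the 95% confidence interval of the fold change on the scale used here lay within 2-fold in either direction. That scale understates the change of dim genes, so for them this is no bound on the change in signal. DAK2, with mean signals of 14.7 in [gar-] and 4.99 in [GAR+], and SPO11, with 2.13 and 7.81, had intervals within 2-fold. On the same scale, 4 probe sets besides HXT3 changed at least 2-fold but did not pass. They were HXT6 at -1.34, the iron siderophore transporter SIT1 at 1.05, and RDN5-1, a 5S ribosomal RNA gene, at -1.11 and the uncharacterised YDR034C-A at 1.08, both of which were picked after their values were seen. How well the poly(A) purification retained the ribosomal RNA of RDN5-1 is not known.

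**Figure D1:**
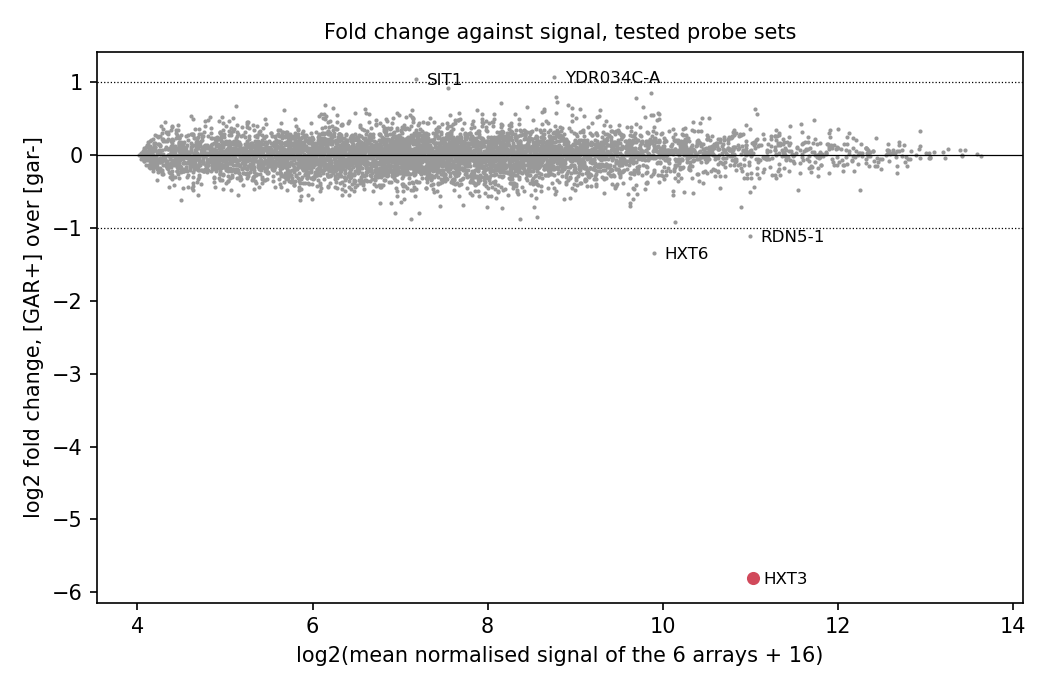
Log2 fold change of [GAR+] over [gar-] (vertical axis) against the log2 of the mean normalized signal of the 6 arrays plus 16 (horizontal axis), 1 point per tested probe set, with dotted lines at a change of 2-fold. HXT3, in red, lies at -5.80, and the 4 other named points are those beyond the dotted lines that did not pass.

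Of the hexose transporter genes, 11 were measured, and 1 of them, HXT3, passed over all genes. Adjusted over the list alone, 2 passed, HXT3 and HXT6. HXT6 encodes a high-affinity transporter, and its signal was 1372 ± 583 in [gar-] and 505 ± 97.0 in [GAR+] (SD, n = 3). Its unadjusted p was 0.000865, its adjusted p over all genes was 1.00, and all 3 [GAR+] values lay below all 3 [gar-] values. HXT7, its close homologue, gave 1331 ± 388 and 1251 ± 290 (SD, n = 3), a change of -0.07. Both probe sets carry the array's suffix for a gene family, and their transcripts are nearly identical, so how much of each signal belongs to each gene is uncertain. HXT1, HXT2 and HXT4 did not pass, with changes of -0.23, 0.31 and 0.24. HXT5, HXT8, HXT10, HXT14 and GAL2 had mean signals under 20 in both groups and gave -0.09, -0.05, -0.30, 0.02 and -0.04. The list as a whole was shifted downward (camera, adjusted p = 0.00882, median -0.07, 8 of 11 below 0), with a median of 0.02 without between-array normalization, where that of all genes was 0.16. This call was lost with an estimated correlation (adjusted p = 0.767) and without HXT3 (adjusted p = 0.245).

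**Figure D2:**
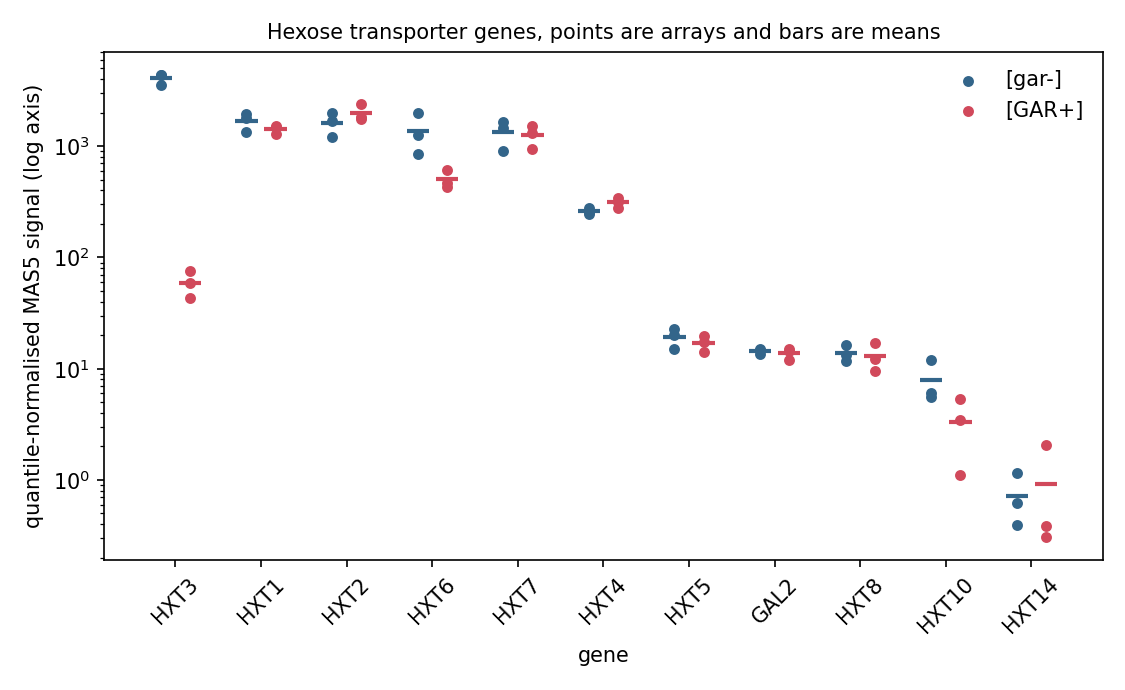
Quantile-normalized signal (vertical log axis) of the 11 measured hexose transporter genes (horizontal axis), with 1 point per array, [gar-] in blue and [GAR+] in red, and a bar at each group's mean. HXT3 falls from 4103 to 59.0, and HXT6 shows non-overlapping groups with means of 1372 and 505.

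Among 25 genes of glucose sensing and repression, 0 passed in limma over all genes and 0 adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.164, median 0.06). MTH1 encodes a repressor of HXT genes that acts with Rgt1. It gave 24.1 ± 4.39 in [gar-] and 46.3 ± 12.4 in [GAR+] (SD, n = 3), a change of 0.62 with an unadjusted p of 0.00650. All 3 of its [GAR+] values lay above all 3 [gar-] values, at signals near the dim end of the array. In [gar-] cultures 1 and 2 MTH1 read 27.4 and 19.1, below the highest non-yeast control of the same array (27.6 and 21.4). STD1, the paralogue of MTH1, gave -0.03 with a standard error of 0.20. PMA1, the plasma membrane proton pump, gave 3462 ± 209 and 3459 ± 368 (SD, n = 3), a difference of -0.005 with a standard error of 0.12. The genes of the glucose sensors SNF3 and RGT2 gave 0.08 and 0.13, and RGT1, the repressor gene, gave -0.01. SNF3 had mean signals of 18.3 in [gar-] and 20.2 in [GAR+], within the range of the highest non-yeast controls, 12.7 to 27.6. MIG2, another repressor gene, gave 0.41, reading 119 in [GAR+] culture 2 against 44.7 and 67.1 in [GAR+] cultures 1 and 3. None of these passed.

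With each gene represented by its probe set of highest mean signal, the 9 genes with the smallest unadjusted p after HXT3, none of which passed, included 7 with lower and 2 with higher signal in [GAR+]. HXT6 was the first of them. The actin-capping gene CAP2 gave -0.85, the ammonium permease gene MEP1 -0.72, the squalene synthase gene ERG9 -0.70, the allantoin pathway gene DAL7 -0.60, RGD3 -0.56 and the dihydroxyacetone kinase gene DAK2 -0.55. The ribosomal protein gene RPS7B gave 0.40 (0.42 by its other probe set) and SAH1, which encodes S-adenosylhomocysteine hydrolase, 0.46. DAK2 passed when adjusted over the list alone, that of 10 genes of glycerol metabolism (adjusted p = 0.0398), at mean signals of 14.7 in [gar-] and 4.99 in [GAR+]. Except on the array of [gar-] culture 3 (16.2 against 12.7), DAK2 read below the highest non-yeast control probe set of the same array. Its signal is thus not clearly above that of the controls.

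Of the 33 gene lists, 3 passed in camera at the preset correlation. Besides the hexose transporters, these were genes of the general stress response, shifted downward (adjusted p = 0.0387, median -0.16, or 0.01 without between-array normalization, against 0.16 for all genes), and of cytosolic ribosomal proteins, shifted upward (adjusted p = 0.00934, median 0.07). Of 30 stress genes, 24 lay below 0, and 0 passed over all genes or adjusted over the list alone. The largest values were those of DDR2 at -0.48 and SOL4 at -0.44. In [GAR+] culture 2 DDR2 read 118, against 404 and 281 in [GAR+] cultures 1 and 3. Of the 81 genes on the ribosomal protein list, 56 lay above 0, and 0 passed either way. The list was taken by name pattern and also holds RPP1, a ribonuclease P gene. RPL9B gave 0.56 and RPL27B 0.42. In [gar-] culture 2 RPL27B read 1631, against 3327 and 3052 in [gar-] cultures 1 and 3. With an estimated correlation the adjusted p was 0.920 for the stress genes and 0.767 for the ribosomal protein genes, so neither call held at that setting. Without [GAR+] culture 2 the median of the stress genes was 0.06 (adjusted p = 0.522), and the call was also lost without [gar-] culture 1 (0.558, median -0.05) or 3 (0.509, median -0.07), while that of the ribosomal protein genes was lost without [GAR+] culture 2 (0.137, median 0.03) or [gar-] culture 1 (0.0820, median 0.04) or 3 (0.132, median 0.06). The arrays of both cultures numbered 2 stood apart on the first principal component, and without both the adjusted p was 0.103 for the stress genes, with a median of -0.11, and 0.00452 for the ribosomal protein genes.

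With the culture number as a block, 7 lists passed, these 3 and 4 more, against 0 with an estimated correlation. The additional lists were amino acid biosynthesis under Gcn4, with a median of -0.06 (adjusted p = 0.0350 blocked, 0.0572 unblocked), and methionine and sulfate assimilation, with -0.14 (0.0350 and 0.0572). The other two were the iron regulon at 0.14 (0.0328 and 0.0572) and cyclins and cell cycle genes at 0.11 (0.0350 and 0.0770). In these lists 26 of 38, 16 of 21, 7 of 23 and 6 of 22 genes lay below 0. Without both arrays numbered 2 and unblocked, the adjusted p of the 4 lists in the same order was 0.106, 0.380, 0.0805 and 0.227, with medians of -0.09, -0.08, 0.12 and 0.11. No member passed over all genes or adjusted over the list alone. Examples are LEU4 at -0.71 and TRP2 at 0.53, MET3 at -0.58 and MET6 at 0.86, SIT1 at 1.05 and FIT2 at 0.45, and PCL1 at 0.47 and SWI5 at 0.45. MET6 and MET3 both serve methionine synthesis and lay on opposite sides of 0. Several of these values rest largely on an array numbered 2. In [gar-] culture 2 MET6 read 229, against 962 and 973 in cultures 1 and 3, and TRP2 305, against 1090 and 879. SIT1 read 31.5 there, against 74.4 and 137. LEU4 read 540 in [GAR+] culture 2, against 2148 and 2007 in [GAR+] cultures 1 and 3.

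No list of energy metabolism passed. The medians and camera's adjusted p were -0.02 and 0.688 for glycolysis and fermentation, 0.08 and 0.688 for the tricarboxylic acid cycle, -0.02 and 0.507 for the respiratory chain and ATP synthase, and -0.08 and 0.214 for glycerol metabolism. They were 0.02 and 0.871 for gluconeogenesis and two-carbon use, where the mean and camera's direction lay below 0, and 0.06 and 0.959 for the use of galactose, sucrose and maltose. With 1 array left out in turn, each of these medians took both signs. That of the tricarboxylic acid cycle ranged from -0.101 to 0.135, and that of glycerol metabolism from -0.193 to 0.026. Single members were HXK1 at 0.66 and PYK2 at -0.50, CIT2 at -0.66 and IDH2 at 0.51, COX7 at 0.34 and COX5B at -0.31, GPP2 at 0.61, YAT1 at -0.39 and SIP4 at -0.34, and MAL13 at 0.27 and GAL3 at -0.25. At each culture number HXK1 was higher and CIT2 lower in [GAR+]. With the number as a block, limma gave HXK1 an unadjusted p of 0.00162, against 0.180 without it. For CIT2 these were 0.00114 and 0.0639, and neither gene passed with the block (adjusted p = 0.735). In [gar-] culture 2 COX7 read 752, against 1504 and 1455 in [gar-] cultures 1 and 3, and GPP2 79.2, against 228 and 227. Transcripts encoded in mitochondria, which cells without mitochondrial DNA lack, had a median of -0.10 (adjusted p = 0.198), with OLI1 at -0.53 and ATP8 at -0.18. The RNA was purified on oligo(dT) resin, and how well it retained these transcripts is not known. The values therefore do not settle whether mitochondrial DNA was present. A second probe set gave -0.14 for OLI1 and 0.41 for ATP8. Mean signals in [gar-] and [GAR+] were 5.30 and 2.97 for ATP8 and 0.497 and 6.07 for its second probe set. The second probe set of OLI1 gave 4.47 and 2.59. These means lie below the highest non-yeast controls, which read 12.7 to 27.6. Those of SIP4, 18.9 in [gar-] and 11.8 in [GAR+], lie within or below that range. Apart from DAK2, no member of these lists passed over all genes or adjusted over the list alone.

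The nutrient, protein and membrane lists gave a median of -0.12 (adjusted p = 0.0940) for nitrogen catabolite repression, 0.07 (0.688) for the phosphate regulon and 0.004 (0.688) for ergosterol and hypoxic genes, where the mean and camera's direction lay below 0. Heat shock proteins and chaperones gave 0.01 (0.959) with a mean of -0.01, the proteasome -0.003 (0.713), ribosome biogenesis 0.06 (0.507), the proton pump and ion transport -0.10 (0.643), and prion protein genes 0.03 (0.788). Apart from ERG9, MEP1 and DAL7, members with the largest values were PHO86 at 0.23 and PHO81 at -0.22, ERG10 at 0.34, MDJ1 at 0.48 and SIS1 at -0.43, RPT5 at -0.45 and PRE5 at -0.37, RPF1 at -0.41 and RRP9 at 0.40, PMA2 at -0.32 and ENA5 at -0.29, and URE2 at 0.25 and PIN2 at 0.22. In [gar-] culture 2 MDJ1 read 60.7, against 202.5 and 206 in [gar-] cultures 1 and 3. ERG10 read 1533 there, against 2616 and 2525, and RRP9 446, against 636 and 606. The 3 other probe sets of RPT5 gave -0.05, 0.13 and -0.06. None passed over all genes or adjusted over the list alone.

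The lists of yeast cell type genes did not pass either. Genes specific to mating type a had a median of 0.14 (adjusted p = 0.449) with MFA1 at 0.63 and AGA2 at 0.22, and those specific to mating type alpha 0.09 (0.319) with MF(ALPHA)1 at 0.39 and MF(ALPHA)2 at 0.19. The medians were 0.02 (0.871) for haploid and pheromone response genes, whose mean and camera's direction lay below 0, and -0.003 (0.959) for meiosis and sporulation. PRM2 gave -0.47, SST2 0.28, SPO11 0.39 and IME4 -0.36. In [GAR+] culture 2 SST2 read 344, against 178 and 180 in [GAR+] cultures 1 and 3. Mean signals in [gar-] and [GAR+] were 2.13 and 7.81 for SPO11, 12.7 and 6.39 for IME4 and 20.6 and 10.4 for PRM2. They were 15.8 and 25.4 for MF(ALPHA)1 and 15.5 and 19.9 for MF(ALPHA)2. The highest non-yeast control probe set of an array read 12.7 to 27.6, so these means lie within or below that range. The genes specific to mating type a read far above it in both groups, with 1670 and 2560 for MFA1 and 241 and 284 for AGA2. That list therefore does not mark a cell type foreign to these cultures. The auxotrophic marker genes, several of which are mutated in W303, had a median of 0.07 (0.688), with CAN1 at 0.45 and ADE2 at 0.30. In [gar-] culture 2 CAN1 read 58.7, against 180 and 158 in [gar-] cultures 1 and 3, and ADE2 84.8, against 153 and 144. The remaining lists were seripauperins at -0.10 (0.214), the subtelomeric COS family at 0.13 (0.245), flocculins and adhesins at 0.06 (0.449), cell wall integrity at 0.06 (0.688) and histones at 0.11 (0.688, with a mean of -0.0004). Their largest members were TIR3 at -0.38 and PAU23 at -0.26, COS8 at 0.48 and COS7 at 0.23, FLO5 at 0.40 and AGA1 at 0.24, SPI1 at -0.38 and YPS1 at -0.32, and HTZ1 at -0.44 and HHO1 at 0.22. Other probe sets gave 0.79 (unadjusted p = 0.00164) and 0.21 for COS8, -0.01 for COS7, 0.17 and 0.52 for FLO5 and 0.43 for MFA1, and none of them passed. The mean signal of FLO5 was 11.6 in [gar-] and 20.7 in [GAR+], also no higher than the range of the controls. No member of these lists passed over all genes or adjusted over the list alone.

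**Figure D3:**
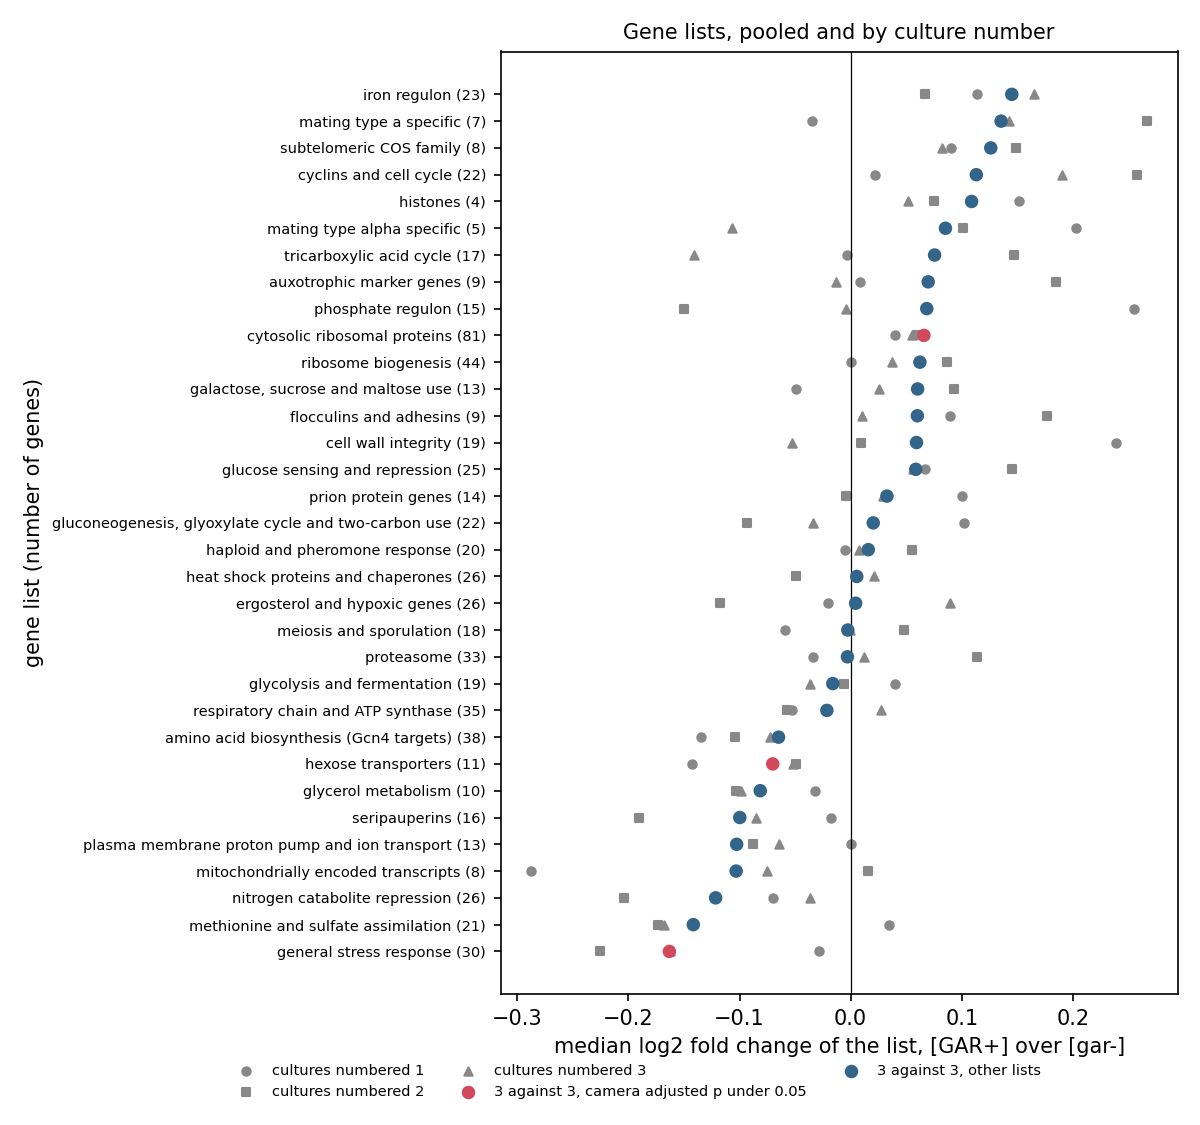
Median log2 fold change of [GAR+] over [gar-] (horizontal axis) for each of the 33 gene lists (vertical axis, number of measured genes in brackets), pooled over 3 against 3 arrays (large points, red where camera's adjusted p was under 0.05) and for each culture number alone (grey). The pooled medians lie between -0.16 for the general stress response and 0.14 for the iron regulon.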

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

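Scaling by the trimmed mean, the fit without both arrays numbered 2 and the lists without HXT3 were chosen after the data were seen. The fit without between-array normalization, first planned for all results, became an alternative after the scales of the arrays were seen. The other alternatives were planned. HXT3 passed in all 20 alternatives, from -6.13 with a pseudocount of 1 to -5.08 with a pseudocount of 64, with a largest adjusted p of 0.000136, and it was the only call in each, leaving 0 higher and 1 lower. HXT6 passed in 0 of 20 (-1.77 to -1.03, smallest adjusted p 0.153). Of 1458 values of the other named genes, 1430 kept direction and side of the threshold and 28, none called, changed sign. The number of gene lists past the threshold moved from 3 to 6 with cyclic loess, 8 with median centring, 1 without the trend, 7 without between-array normalization, 7 with scaling by the trimmed mean, 0 with an estimated correlation, 0 with fry and 1 without HXT3. It was 2 to 12 with 1 array left out, 12 without [gar-] culture 2. The number of probe sets at an unadjusted p under 0.05 in limma ranged from 35 without between-array normalization to 441 with the block. The replicate block gave 7 lists and changed no other call. The 4 lists it added moved with single arrays left out, unblocked. The median of the iron regulon ranged from 0.009 (without [gar-] culture 1, adjusted p = 0.558) to 0.219 (without [GAR+] culture 1, 0.00374), that of cyclins and cell cycle genes from 0.007 (without [GAR+] culture 2, 0.655) to 0.268 (without [GAR+] culture 1, 0.00254), that of methionine and sulfate assimilation from -0.268 (without [gar-] culture 1, 0.00468) to -0.031 (without [gar-] culture 2, 0.503), and that of amino acid biosynthesis under Gcn4 from -0.130 (without [gar-] culture 3, 0.0226) to -0.049 (without [gar-] culture 2, 0.228). Of 656 list values, 538 were the same, 39 gained and 19 lost the call, 2 reversed and 58, none called, changed sign. The median of the general stress response ranged from -0.324 (without [gar-] culture 2) to 0.0641 (without [GAR+] culture 2) with 1 array left out, and that of heat shock proteins from -0.294 to 0.318 with the same arrays left out. Ribosomal protein genes kept their upward direction throughout but missed the threshold without the trend (adjusted p = 0.0541), without [GAR+] culture 2 (0.137) and without [gar-] culture 1 (0.0820) or 3 (0.132). The stress genes missed it with cyclic loess (0.0598), without the dimmest probe sets (0.0795), without the trend (0.0541), with array weights (0.104), without both arrays numbered 2 (0.103), and without [GAR+] culture 2 (0.522) or [gar-] culture 1 (0.558) or 3 (0.509). Taking HXT3 out of every list put their adjusted p at 0.0580. The stress list does not hold HXT3, and its median stayed at -0.16. This miss came from the adjustment over the lists, where the hexose transporters no longer passed (0.245). Without between-array normalization the median of all genes was 0.16, and the medians of hexose transporters and stress genes, 0.02 and 0.01, lay below it. The cause of the other changes in calls was not tested. The filter at a background level was not run, because no such level was called, so how far signal over background limits dim genes is open. No list value was computed for the robust fit, all probe sets or 1 probe set per gene.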

Other observations

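Of the tests in this part, the count over splits of the arrays, leaving out single arrays and the culture number as a block were chosen before their results were seen. The genes next to HXT3, the comparison of HXT6 with HXT7, the contrast between culture numbers, leaving out both arrays numbered 2, and the question whether a single array decides the shift of the stress genes were chosen afterwards, as were the tests of the heat shock genes.

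No neighbour of HXT3 on the chromosome passed. Of 24 genes within 12 steps on each side of HXT3, 21 had a tested probe set. In limma 0 of these passed and 1, HXT6, had an unadjusted p under 0.05. HXT6 lies 2 steps from HXT3 and HXT7 lies 3 steps away on the same side. SVF1, next to HXT3 on the other side, gave 0.19. The neighbours other than HXT6 lay between -0.20 and 0.42. For 20 of the 21 the 95% confidence interval on the scale used here stayed within 2-fold. Among 2831 probe sets outside the test, controls and those of several or no named genes, 0 passed, 152 had an unadjusted p under 0.05 and the smallest adjusted p was 0.408. Of the 10 ways to split the 6 arrays 3 against 3, 1 gave as many calls as the real grouping, the real one itself with 1 call, and the highest of the others was 0. With 10 splits the share cannot fall under 0.05. Every other split mixes arrays of high and low HXT3 signal, so HXT3 could not be called there. The arrays are also not freely exchangeable, since same-numbered ones correlate. This count is therefore no evidence about chance.

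More probe sets separated the cultures numbered 2 from the other 4 than separated the prion groups. The arrays numbered 2 lay apart from the others on the first principal component (39.7% of the variance). On the second (25.8%) they lay at opposite ends, at 19.8 for [gar-] culture 2 and -13.5 for [GAR+] culture 2. The 2 cultures thus also differed from each other. A separate limma fit for each number, with the group as a term, set that number against the other numbers together. Number 2 gave 111 probe sets past an adjusted p of 0.05 (24 higher, 87 lower). Number 1 gave 1 and number 3 gave 0. Genes for heat shock proteins and chaperones had a median log2 difference of -0.80 in number 2, -0.83 in [gar-] and -0.84 in [GAR+], with 9 of 26 lower over all genes and 21 adjusted over the list alone, where 1 was higher. The 26 include SBP1, an RNA-binding protein gene that entered the list through the name SSB1. The chaperone gene HSP82 gave -2.40, BTN2 -2.13, SIS1 -1.70, HSP10 -1.49, HSP78 -1.22 and the disaggregase gene HSP104 -1.18. Camera gave the list an adjusted p of 2.31e-15, and an adjusted p of 0.0853 with an estimated correlation. General stress genes had a median of -0.59 (adjusted p = 2.72e-12), proteasome genes -0.33 (adjusted p = 4.76e-07) and ribosome biogenesis genes 0.23 (adjusted p = 4.00e-05). With an estimated correlation the adjusted p of these lists was 0.178, 0.361 and 0.361. The cell wall mannoprotein gene TIP1 (1.51), IZH4 (1.39) and PLB2 (1.18) were higher in number 2. In the counts of lists past the threshold the numbers differed less, with 12 for number 2, 7 for number 1 and 9 for number 3, and 0 for each with an estimated correlation.

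For the lower heat shock genes of number 2, neither array brightness nor loss of 5' transcript ends was excluded. The [gar-] cultures 1 and 2 had nearly equal trimmed means (295.35 and 295.43), and on their deposited signals the median heat shock gene differed by -0.67, with 25 of 26 genes lower in culture 2. This is 1 array against 1, and [GAR+] culture 2, whose array was the dimmest, had none of similar brightness in its group. Loss of 5' transcript ends would raise the 3' over 5' ratios of control transcripts. In 0 of 3 such controls were both arrays numbered 2 above the other 4, and for actin both were below them, but in 2 of 3 one of them was the highest, with 9.72 in [gar-] culture 2 for YER022W and 3.41 in [GAR+] culture 2 for TBP. The design names nothing that the number 2 stands for, so no biological explanation was tested, and a shared day or handling of these cultures stays open.

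A scaling factor shared by all probe sets of an array does not explain the lower HXT6 signal in [GAR+]. The ratio of HXT6 to HXT7 within an array, which no such factor alters, was 2.49 times lower in [GAR+] with no overlap. The difference of the log2 ratio was -1.32, and the exact permutation test gave p = 0.1, the smallest possible. Effects of brightness that differ between the 2 probe sets would not cancel in this ratio, so it cannot exclude them. The ratio was chosen after both signals were seen. Whether the HXT6 probe set also binds some HXT3 transcript, or HXT6 itself was lower in [GAR+], stays open, because the probe sequences were not used here.

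Whether the downward shift of general stress genes in [GAR+] rests on a single array stays open. With [GAR+] culture 2 left out, their median went from -0.16 to 0.064, while with [gar-] culture 2 left out it was -0.32. General stress genes were lower in both cultures numbered 2, so leaving out 1 of them makes the groups unequal in these cultures. With both left out the median was -0.11 (adjusted p = 0.103), and within the culture numbers 1, 2 and 3 it was -0.03, -0.23 and -0.16. A difference of the prion state in these genes stays open, since the list passed with the culture number as a block (adjusted p = 0.00281), though not with an estimated correlation there (adjusted p = 0.689). The hexose transporters, HXT3 among them, had the same adjusted p of 0.689 in camera at that setting, so this miss decides little.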
